A study of Stylophora pistillata with 18 samples.

How the data were processed

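RNA was sequenced from specimens of 2 adult colonies of the stony coral Stylophora pistillata after 18 h in seawater, in seawater with 250 µM 3'3'-cUA or in seawater with 250 µM 2'3'-cGAMP. Each treatment had 6 libraries, 3 per colony, and all 18 libraries entered the analysis. Libraries are named by treatment, colony number and specimen letter, as in control 1A. Per the labels' protocols, total RNA was extracted on columns with DNase treatment, messenger RNA was enriched on oligo(dT) beads, and libraries were made with a directional kit, which marks the strand of the transcript.

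The deposited values are counts of reads per gene model, whole numbers with a different total in each library, so no normalization had been applied to them. STAR, featureCounts and DESeq2 are named per the submitters' processing notes; their versions, roles and settings, the genome build, the counted feature, the strand setting and the treatment of reads that match several places are not given in the sources used here. Reads of overlapping models, of antisense partners and of near-identical copies may therefore have been split or lost in ways that could not be checked. A deposited annotation gave the positions of 29419 models on 3122 scaffolds, of which 24830 came from the predictor Gnomon, 4332 from AUGUSTUS and 13 from RefSeq, while 244 had no named source. Coordinates are given as that annotation states them.

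The models carried no product names. A reference gene table of the assembly jaStyPist1.2, which is not the assembly of the deposited coordinates, was used for symbols alone. By protein accession 13548 models were matched to it, 4855 with the same version of the accession and 8693 with another version. All but 1 of the matched symbols were LOC numbers without a description. The 30 gene lists fixed in advance, covering cyclic dinucleotide sensing, antiviral and inflammatory pathways, cell death, calcification, symbiosis and markers of other cell types, were defined by product descriptions. None of the 30 had a matched member, so all of the gene list tests are void and were not run. The rule for named genes set before the data were examined asked for the models with the largest changes and an informative description; where no description could be had, it allowed at most 2 identifiers that rose and 2 that fell per comparison. These were the called models with the largest log2 fold change in each direction, a mean of at least 1 CPM over all libraries and the same sign in both colonies. The single model with a symbol that is not a LOC number, Cglr2, was added for its symbol. Any other model, region or set named below was chosen after its values were seen.

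Total counts per library ran from 22175801 to 41800393. The precision of a model thus depends on its own count, and ratios of summed counts are given with exact 95% intervals, which cover counting error only. Of the 29419 models, 873 had no count in any library. The 21375 models that passed edgeR's filterByExpr with the 6 treatment-by-colony groups were tested. The lowest chi-square per degree of freedom between libraries of the same group was 21.2, so no pair of libraries differed by sampling noise alone. Each library was counted as a replicate, but this spread does not show that specimens of the same colony are independent.

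Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, robust quasi-likelihood fits and a model of colony plus treatment over all 18 libraries, which left 14 residual degrees of freedom. The interaction of colony and treatment was tested in a second model with 12 residual degrees of freedom. A model was called at an adjusted p below 0.05 by the Benjamini-Hochberg method, and all adjusted p-values of single models below come from these edgeR tests. The common biological coefficient of variation was 0.464. Group levels are given as CPM scaled by TMM, mean ± SD, and log2 fold changes with their standard errors. Log2 CPM used a prior count of 2.

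For a direct comparison of the compounds, models called in the average of both compounds against seawater were collected into a set that rose and a set that fell, and the mean log2 CPM of each set was computed per library. Averaging both compounds gives them equal weight in the choice of the sets. The choice may still lean to the compound with the larger spread, and cUA scores varied more. Their SD was 0.328 against 0.123 for cGAMP in the set that fell and 0.258 against 0.192 in the set that rose. Differences of such scores were tested by exact two-sided permutation of the library labels, and the difference between colonies by exact permutation of colony labels within each treatment. Neither keeps the colonies apart, so both were repeated with treatment labels permuted within each colony, an alternative added after the data were seen. The association of calls with position was tested by permuting the order of tested models within the annotation 1000 times. Values for unchanged groups that share the control libraries came from 20 simulations, which drew each model independently of the others. The controls were also split in 18 ways, so that each compound was set against other control libraries.

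The comparisons, their tests and a list of alternatives were chosen before the data were examined. The listed alternatives were other scalings (size factors of the DESeq2 type, upper quartile, total counts only), no low-count filter or a stricter one of 1 CPM in at least 6 libraries, DESeq2 1.42.0, limma-voom with sample weights (limma 3.58.1), models without colony or with the specimen letter as a replicate block, fits within each colony or of only the treatments compared, and leaving out each library in turn. Alternatives added after the data were seen were 2 surrogate variables (sva 3.50.0), libraries thinned to equal depth, limma-voom without sample weights, and the analysis with neither control 1A nor cUA 2A. Scores, permutations and figures were made with Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.

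The procedure was tested on simulated data with the real means, library sizes and 21375 models, each drawn independently. In these, 200 models were changed for each compound, for colony and for each interaction. More models were called in the real comparisons with control than were planted, which loosens the adjusted threshold. Recovery there may therefore have differed from the values below. For cUA against control it recovered 10.4%, 64.2% and 78.8% of models planted at log2 changes of 1, 2 and 3, and for cGAMP against control 20.9%, 64.2% and 90.9%. For cUA against cGAMP, read on the models planted for cUA, it recovered 16.4%, 67.2% and 81.8%, and for the colony difference 31.3%, 80.6% and 90.9%. For the interaction with cUA it recovered 0%, 11.9% and 27.3%, and for that with cGAMP 0%, 2.99% and 33.3%.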

Results

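Gene expression was measured by RNA sequencing in adult Stylophora pistillata, a reef-building coral, to ask how cyclic dinucleotides that cGAS-like receptors make alter its transcripts. cGAS and its relatives are enzymes that produce cyclic dinucleotides as second messengers, and in vertebrates 2'3'-cGAMP from cGAS activates the receptor STING. 3'3'-cUA carries uracil and adenine and 2'3'-cGAMP guanine and adenine, and the compounds also differ in the linkage between their nucleotides. Specimens of 2 colonies were held for 18 h in seawater alone or with 250 µM of either compound, which gave 6 libraries per treatment and 3 per treatment and colony. Total counts ran from 27090845 to 41800393 in the control libraries, from 24307409 to 34361709 with cUA and from 22175801 to 28033513 with cGAMP. The labels call the libraries specimens of a colony without saying how independent they were, so the p-values measure the spread between these specimens.

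The first principal axis of log2 CPM, with 30.4% of the variance, held the control libraries at its low end, from -91.9 to -31.8, and the cGAMP libraries between 27.2 and 73.2. The cUA libraries spread from -33.5 to 131, with cUA 2A at the far end. The second axis, with 24.1% of the variance, parted libraries inside each treatment. Control 1B and 1C, cUA 1C and 2B, cGAMP 1A, 1B, 1C and 2C lay above 0 on it and the other libraries below, so that it did not follow the colony labels in control 1A, cUA 1A, 1B and 2B and cGAMP 2C. Control 1A and cUA 2A also had the lowest composition factors, 0.714 and 0.619, against 0.862 to 1.23 in the other libraries, and each main count is therefore given without them too.

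**Figure D1:**
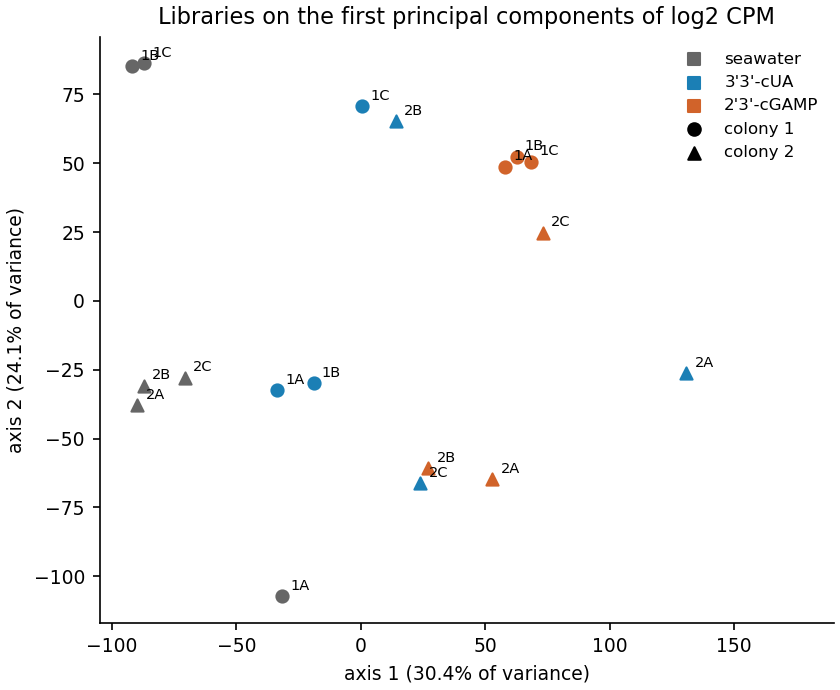
Positions of the 18 libraries on the first principal components of log2 CPM (axis 1, 30.4% of variance; axis 2, 24.1%), with treatment as colour, colony as symbol and the colony number and specimen letter beside each point. Control libraries lie at the low end of axis 1, cUA 2A lies at 131, and axis 2 does not separate the colony labels.

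The comparison of 3'3'-cUA with seawater asked which transcripts change with a cyclic dinucleotide of the uracil and adenine type. Transcripts of 1263 gene models rose and those of 916 fell, 10.2% of the 21375 tested. Among the called models 959 of the rises and 744 of the falls were over 2-fold, with median log2 fold changes of 1.63 and -1.56, while over all tested models the median absolute log2 fold change was 0.35. Many of the called models lay next to each other in the genome.

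Among models that rose with cUA, LOC111344807 (Spis_XP_022807804_1, a single coding segment on the minus strand of scaffold NW_019218567.1, 74254 to 75426) had the largest change, with a log2 fold change of 6.81 ± 1.69 (SE, adjusted p = 0.0145). It was nearly silent in seawater, with 2 counts in the 6 control libraries together against 266 with cUA, a ratio of 156 after scaling by depth (95% interval 42.7 to 1290). Of those 266 counts 223 came from cUA 2A, and without that library the log2 fold change was 4.29 (adjusted p = 0.0324). Its call was lost in each colony alone and with limma-voom with or without sample weights (adjusted p from 0.00033 to 0.229 over the alternatives that gave a value, which DESeq2 and the stricter filter did not). LOC111342923 (Spis_XP_022805782_1, plus strand of NW_019218379.1, 18160 to 19301) followed at 6.14 ± 1.28 (adjusted p = 0.00449), with 5 control counts against 312, a ratio of 73.0 (95% interval 31.0 to 226). There too cUA 2A held 219 of the 312 counts, and the log2 fold change was 4.40 without it, and the call was lost in colony 1 alone (adjusted p = 0.103, the highest over the alternatives).

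Among models that fell, LOC111330992 (Spis_XP_022791745_1, 4 coding segments on the plus strand of NW_019217946.1, 352520 to 355023) went from 3.00 ± 1.25 CPM in seawater to 0.0455 ± 0.0469 CPM with cUA (SD, n = 6), a log2 fold change of -5.89 ± 0.74 (adjusted p = 4.49e-05). LOC111347646 (Spis_XP_022810608_1, plus strand of NW_019219330.1, 14374 to 16826) had a log2 fold change of -5.14 ± 1.31 (adjusted p = 0.0170), but control 1A held 1140 of its 1316 control counts and the log2 fold change was -2.35 without that library. Its call was lost in each colony alone, with the libraries of both treatments alone and with unweighted limma-voom (adjusted p from 0.000419 to 0.183 over the alternatives that gave a value, again without DESeq2 and the stricter filter). Cglr2 (Spis_XP_022802921_1, minus strand of NW_019218231.1, 193575 to 195716), whose symbol names it as a cGAS-like receptor, stood at 3.87 ± 1.83 CPM in seawater and 5.05 ± 1.94 CPM with cUA (SD, n = 6). Its log2 fold change of 0.38 ± 0.35 did not pass the test (adjusted p = 0.578). Among the alternatives only the model with surrogate variables called it (adjusted p = 0.0416).

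The count of 2179 models came from edgeR's quasi-likelihood test, in which 4983 models had an unadjusted p below 0.05 where 1069 are expected by chance. It was 2959 without control 1A and cUA 2A, 3392 without control 1A alone and 1369 without control 2A. With other tests and samples it was 3269 with DESeq2, 6144 with limma-voom and sample weights, 4906 with surrogate variables, 931 in colony 1 alone and 471 in colony 2 alone. The balance of rises and falls turned with upper quartile scaling (1109 and 1149) and with limma-voom and sample weights (2715 and 3429), and was even without control 2C (1004 and 1003).

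The comparison of 2'3'-cGAMP with seawater asked the same of the dinucleotide that vertebrate cGAS makes. With cGAMP 1970 models rose and 2634 fell, 21.5% of those tested. Over 2-fold were 1301 of the rises and 2086 of the falls, and the median log2 fold changes of the called models were 1.31 and -1.49. Among those that rose were transcripts of 6 of the 12 tested models of the mitochondrial genome.

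LOC111342923 rose most with cGAMP, with a log2 fold change of 6.72 ± 1.26 (adjusted p = 0.000947) and 392 counts against 5 in seawater, a ratio of 116 (95% interval 49.5 to 361). LOC111344807 followed at 6.16 ± 1.66 (adjusted p = 0.0126), with 121 counts against 2 and a ratio of 89.8 (95% interval 24.3 to 750). These were the same models that rose most with cUA, and their calls were lost in colony 2 alone, at log2 fold changes of 6.93 for LOC111342923 and 7.36 for LOC111344807, that of LOC111344807 in colony 1 alone too, at 5.47 (adjusted p up to 0.057 for LOC111342923 and 0.201 for LOC111344807 over the alternatives that gave a value). LOC111330992 fell to 0.0449 ± 0.0701 CPM (SD, n = 6), a log2 fold change of -5.95 ± 0.76 (adjusted p = 2.87e-05). LOC111339328 (Spis_XP_022801703_1, minus strand of NW_019218186.1, 81435 to 82449) went from 28.6 ± 24.5 CPM in seawater to 0.825 ± 0.71 CPM with cGAMP (SD, n = 6), a log2 fold change of -5.30 ± 0.80 (adjusted p = 0.000139), and stood at 5.26 ± 3.48 CPM with cUA. Cglr2 stood at 5.97 ± 2.21 CPM with cGAMP, a log2 fold change of 0.56 ± 0.35 that did not pass the test (adjusted p = 0.280). Here too only the model with surrogate variables called it (adjusted p = 0.00263).

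The mitochondrial models were chosen as a set after their values were seen. Their spans overlap: that of Spis_YP_002149701_1, 2008 to 14429, contains those of most others, and adjoining models overlap or abut between 11786 and 13247. How reads of overlapping models were counted is not known, so the models are not separate pieces of evidence. Of 12 tested on the mitochondrial scaffold NC_011162.1, 6 rose with cGAMP and 0 with cUA by edgeR, where 9 and 2 were higher at an unadjusted p below 0.05. DESeq2 called 8 as higher with cGAMP and 0 with cUA, and limma-voom with sample weights called 10 as higher with cGAMP and 7 as lower with cUA. In colony 1 alone edgeR called 8 as higher with cGAMP and 3 as lower with cUA, and in colony 2 alone 0 as higher with either compound. The models that edgeR called as higher with cGAMP over all libraries stood at 0.272 to 6.84 CPM in seawater. The most abundant mitochondrial model, at 81.7 ± 22.9 CPM in seawater and 111.5 ± 31.8 CPM with cGAMP (SD, n = 6), was not called (edgeR, adjusted p = 0.289). The mean log2 CPM of the 12 models, which weighs each alike, was 1.80 ± 0.410 in seawater, 1.83 ± 0.617 with cUA and 2.85 ± 0.702 with cGAMP (SD, n = 6). The difference of 1.05 in this score between cGAMP and seawater was larger than the spread between libraries (exact permutation test, p = 0.00216) and lay between 0.899 and 1.06 under the other scalings. All 6 cGAMP libraries, at 2.19 to 3.94, lay above the highest control library at 2.17. Larger than the spread too was that of -1.02 between cUA and cGAMP (95% interval -1.87 to -0.173, exact permutation p = 0.0238), though not with labels permuted within colonies (exact permutation p = 0.055). That difference came from colony 1, where it was -2.05 (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow), while it was 0.00253 in colony 2 (exact permutation p = 1). The cGAMP effect against seawater was 1.33 in colony 1 and 0.773 in colony 2. The cUA effect on this score was -0.716 in colony 1 and 0.775 in colony 2, and these differed by -1.49 (exact permutation of colony labels within treatments, p = 0.005, adjusted p = 0.03 over 6 such tests). With treatment labels permuted within colonies the exact permutation p was 0.01 and did not pass after adjustment (adjusted p = 0.06). The first permutation assumes no colony difference and the second no treatment effect, so neither tests the interaction alone. The difference was -0.937 with total counts only. No single mitochondrial model was called for the interaction with cUA by edgeR (smallest adjusted p = 0.318). The score moved with library composition in part: cUA 2A and 2C, at 2.72 and 2.50, had the lowest composition factors of the cUA libraries (0.619 and 0.862) and the highest shares of counts in their 50 most abundant models (24.4% and 22.7%), while cUA 2B, with a factor of 1.12, stood at 1.57. Likewise cGAMP 1A, with the lowest factor and highest share of the cGAMP libraries (0.886 and 22.3%), had the highest score, 3.94, but control 1A, at 2.09, lay among the other colony 1 controls.

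The count of 4604 models for cGAMP came with 7238 models at an unadjusted p below 0.05, and scaling by total counts alone changed its balance from 42.8% to 32.1% rising, as the median log2 fold change of all models went from -0.07 to -0.24. The count was 7484 without control 1A and cUA 2A, 10788 with limma-voom and sample weights, 7979 with surrogate variables, 2726 in colony 1 alone and 813 in colony 2 alone. In colony 2 alone the balance turned, with 527 rising and 286 falling.

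The compounds were compared directly at the same dose and time. Most cUA calls were shared, since 1058 models rose and 812 fell with both, 83.8% and 88.7% of the cUA calls. A further 912 rises and 1822 falls were called with cGAMP alone, and 205 and 104 with cUA alone. Calls with a single compound do not show a difference between the compounds. By edgeR 0 models were called in opposite directions, where 3 were opposite at an unadjusted p below 0.05. DESeq2 called 0 in opposite directions and limma-voom 8 with sample weights and 0 without. By edgeR 1 was opposite in colony 1 alone, 1 without cUA 2A and 2 with surrogate variables. The mean log2 CPM of the 1988 models in the set that rose was 2.79 ± 0.0981 in seawater, 4.09 ± 0.258 with cUA and 4.33 ± 0.192 with cGAMP (SD, n = 6). That of the 2608 models in the set that fell was 2.79 ± 0.326, 1.67 ± 0.328 and 1.28 ± 0.123.

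**Figure D2:**
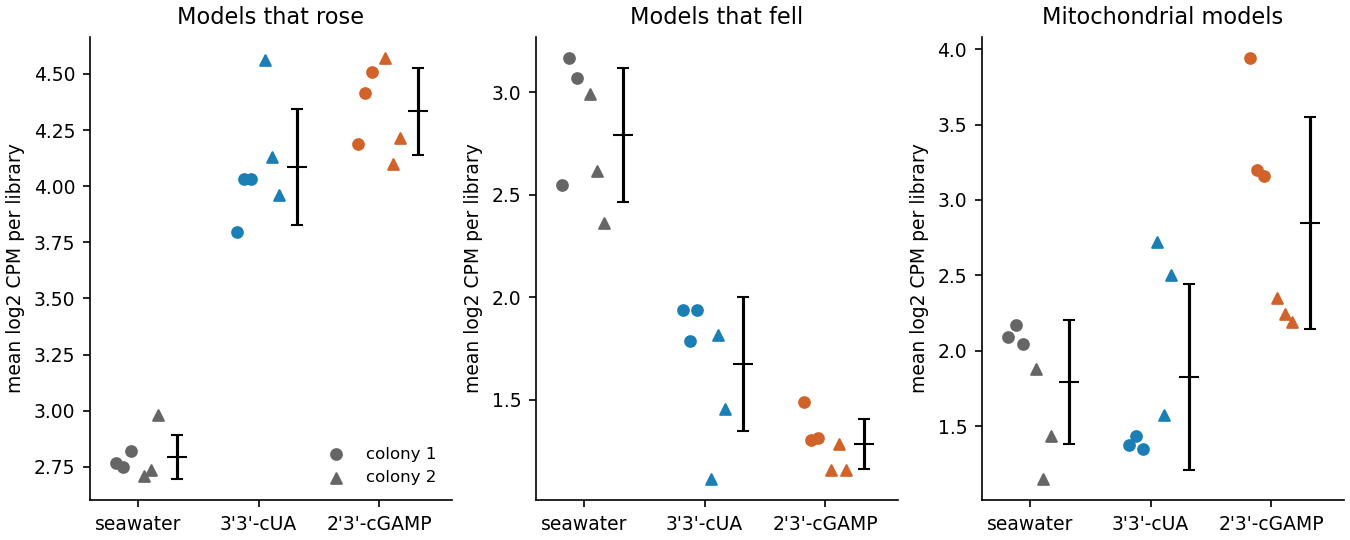
Mean log2 CPM per library (vertical axis) of the 1988 models that rose, the 2608 models that fell and the 12 mitochondrial models, by treatment; circles are colony 1 libraries, triangles colony 2 libraries, and bars mean ± SD (n = 6). In the first panel every treated library lies above every control library and in the second every treated library lies below, while the cUA and cGAMP libraries overlap in both.

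The cUA score lay below the cGAMP score by -0.248 in the set that rose (95% interval -0.54 to 0.045, exact permutation test, p = 0.0801, adjusted p = 0.0801 over 2 sets) and above it by 0.391 in the set that fell (95% interval 0.0729 to 0.709, exact permutation p = 0.0346, adjusted p = 0.0692). In colony 1 the differences were -0.417 and 0.519 (exact permutation p = 0.1 each, the smallest that 3 against 3 libraries allow) and in colony 2 they were -0.0779 and 0.263 (exact permutation p = 0.7 and p = 0.4). Neither pooled difference passed after adjustment, with adjusted p-values from 0.00866 to 0.158 over the alternatives. With treatment labels permuted within colonies, a test added after the data were seen, that of the set that fell passed (exact permutation p = 0.02, adjusted p = 0.04) and that of the set that rose did not (exact permutation p = 0.09, adjusted p = 0.09). Without cUA 2A, the library with the highest rise and the deepest fall among the cUA libraries, the differences were -0.343 and 0.504, each with an adjusted p of 0.00866 by the exact permutation test. The sets were still those chosen with cUA 2A included, so these values are not free of that library. Within the sets, 77.7% of the models that rose and 81.2% of those that fell changed less with cUA than with cGAMP. The sets were chosen by their change against seawater in these libraries, so the scores are no test of that change.

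Model by model, 0 differed between cUA and cGAMP by edgeR, with 1830 at an unadjusted p below 0.05 and a smallest adjusted p of 0.132. LOC111339328 differed by a log2 fold change of 2.73 ± 0.72 (adjusted p = 0.330). DESeq2 called 103 models, limma-voom 2836 with sample weights and 0 without, the surrogate variable model 195, and the fit of colony 1 alone 2. The count was 729 without control 1A and cUA 2A, 45 without cUA 2A alone, 2 without cGAMP 2C and 1 without control 1A. The typical unadjusted 95% interval reached 0.69 to either side on the log2 scale, and in simulated data the adjusted test found 16.4% of models that differed by a log2 fold change of 1 and 67.2% of those that differed by 2, so the compounds are not shown to act alike.

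Across the 21375 models the fold changes of the compounds had a Pearson correlation of 0.86 and a covariance of 0.779, where models are not independent replicates. Both comparisons use the same control libraries. Unchanged groups simulated against these controls gave a correlation of 0.494, a covariance of 0.102 and no calls (20 simulations), and the observed covariance exceeded the simulated one by 0.677. The simulations drew each model independently, while models in the real libraries also varied together, as along the second axis above. They therefore do not show how far these values or the calls could move by chance in such libraries. Independent lists of these sizes would share 116 models that rose and 113 that fell. With the controls split between the compounds, the median over 18 splits was a correlation of 0.643 and a covariance of 0.66, with 506.5 models rising and 343 falling with both, where independent lists would share 34.5 and 38.9.

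**Figure D3:**
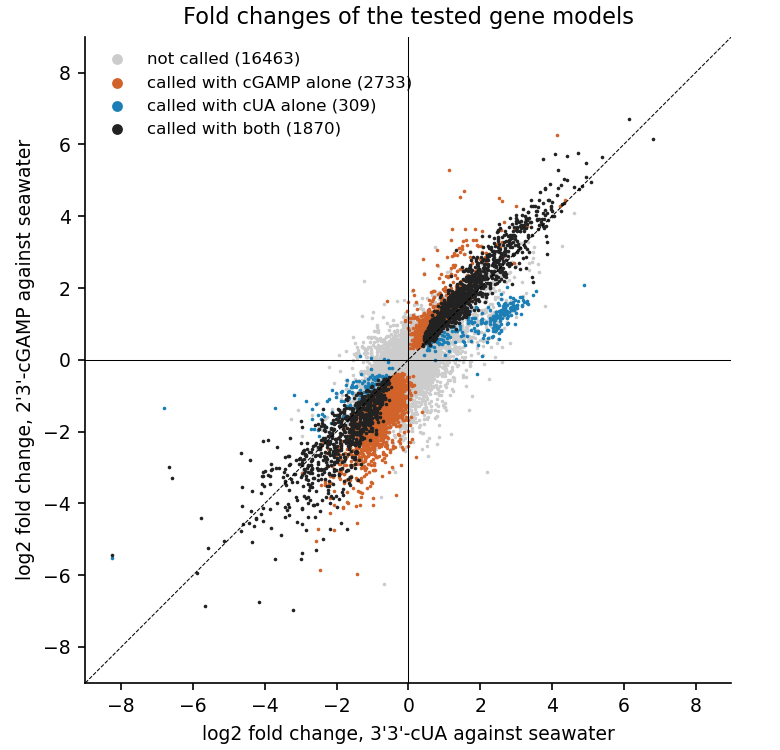
Log2 fold change of each of the 21375 tested models with 2'3'-cGAMP (vertical axis) against that with 3'3'-cUA (horizontal axis), both against seawater; colour shows in which comparison the model was called, and the dashed line marks equal change. Called models lie along the line, with a Pearson correlation of 0.86 over all models, to which the shared controls contribute.

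Models that rose with both compounds often lay side by side. These regions were chosen after their values were seen. Of the 1058 models that rose with both, 349 (33.0%) had at least 1 neighbour among them, and 7 runs held 5 or more adjacent tested models, where the longest run in permuted orders was 5. The longest run, 9 models within 68.3 kb of scaffold NW_019217860.1 (377407 to 445659), was on both strands, 5 models on the plus and 4 on the minus strand, and summed to 464 ± 242 CPM in seawater, 4170 ± 1220 CPM with cUA and 5900 ± 2210 CPM with cGAMP (SD, n = 6). That was 8.99-fold and 12.7-fold above seawater, with log2 fold changes of single models from 2.49 to 3.36 with cUA and from 2.51 to 3.95 with cGAMP. Coding lengths were 534 to 684 bases on the minus strand and 963 to 1131 bases on the plus strand. The models of each strand may thus be copies that share reads, which was not tested, so their single values are uncertain. In this run and the next longest, the span of 1 model overlaps another, where reads of opposite strands can be told apart only if strand was counted.

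**Figure D4:**
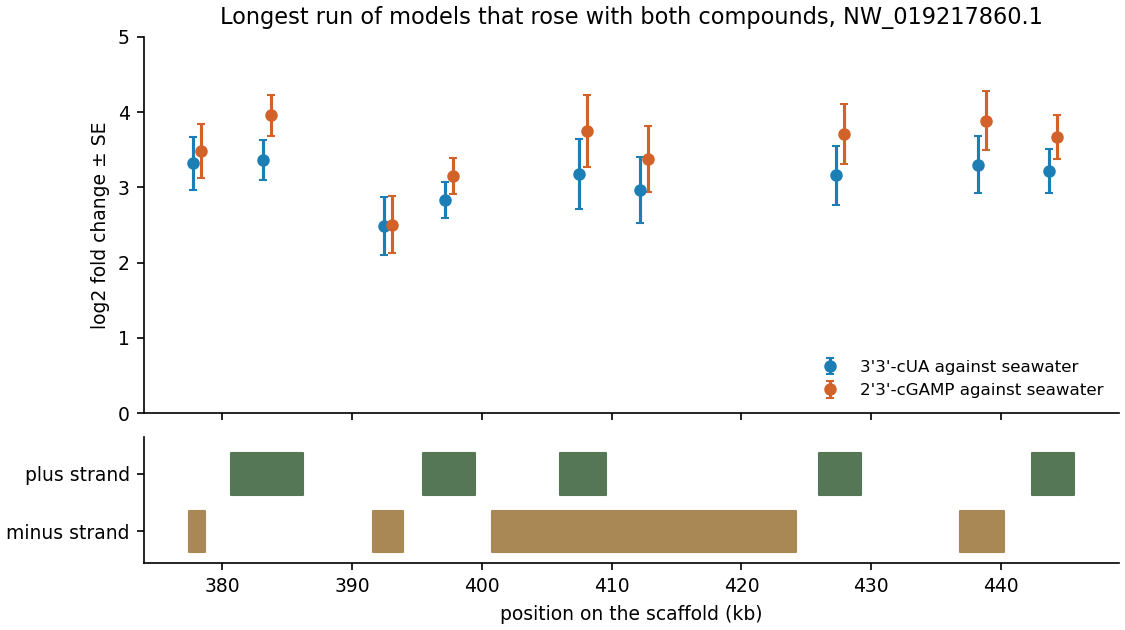
Log2 fold change ± SE of the 9 models of the longest run against their position on scaffold NW_019217860.1 (kb), for both compounds against seawater, with the extent and strand of each model underneath. Every model lies between 2.49 and 3.95 with both compounds, on both strands. Whether the models share reads was not tested.

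A second run held 7 models on NW_019218118.1 (96635 to 145526), which summed to 78.5 ± 26.9 CPM in seawater, 406 ± 62.1 CPM with cUA and 509 ± 125 CPM with cGAMP (SD, n = 6). Runs of 6 models lay on NW_019217841.1 (564953 to 611915), NW_019217936.1 (275603 to 291986), NW_019217968.1 (188670 to 223978) and NW_019218225.1 (27733 to 90576), and a run of 5 on NW_019218191.1 (61786 to 120994). Their sums rose by 3.01-fold to 11.2-fold with cUA and by 3.09-fold to 15.8-fold with cGAMP. The 11.2-fold value, of NW_019218191.1, came from 30.2 ± 6.84 CPM in seawater and 339 ± 354 CPM with cUA (SD, n = 6), a spread larger than the mean. The 6 models on NW_019217936.1 were alike in coding length, 519 to 585 bases within 16.4 kb, and models of near-identical sequence can share reads, so their single values are uncertain.

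Adjacent models were called together more often than in permuted orders of the models. With cUA 240 adjacent pairs rose together where permuted orders gave 67.6 on average, and 156 fell together where 35.8 were expected. With cGAMP 394 pairs rose together against 165 and 571 fell together against 294. Each was above all of the 1000 permuted orders (permutation test, p = 0.000999, the smallest these permutations can give).

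The comparison of the colonies asked how far these effects depended on the colony. Between colony 2 and colony 1, edgeR called 0 models, with 1773 at an unadjusted p below 0.05 and a smallest adjusted p of 0.576. DESeq2 called 3, limma-voom 4510 with sample weights and 0 without. The count was 272 without control 1A and 99 without control 1A and cUA 2A.

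Fold changes were also computed from separate libraries, with no control in common. Over 20058 models the correlation between the colonies was 0.362 for cUA and 0.692 for cGAMP, while cUA in colony 1 correlated at 0.484 with cGAMP in colony 2 and cUA in colony 2 at 0.655 with cGAMP in colony 1. The difference between these correlations was not tested, and models are not independent replicates. In colony 1 alone cUA raised 474 models and lowered 457, and in colony 2 alone it raised 392 and lowered 79. For cGAMP the counts were 1196 and 1530 in colony 1 and 527 and 286 in colony 2.

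The interaction of colony and treatment was called in 0 models by edgeR for either compound, and in 0 without control 1A and cUA 2A. For cUA 2571 models had an unadjusted p below 0.05 and the smallest adjusted p was 0.318, and DESeq2 called 227 models and limma-voom 321 with sample weights and 0 without. The count was 92 without cUA 2B and 1 without cUA 1C. For cGAMP 1119 models had an unadjusted p below 0.05, near the 1069 expected by chance, with a smallest adjusted p of 0.884, and DESeq2 called 4 models and limma-voom 828 with sample weights and 0 without. In simulated data the adjusted test found 11.9% and 2.99% of interactions of 2 on the log2 scale, and 27.3% and 33.3% of those of 3, for cUA and cGAMP, so most differences of these sizes between the colonies were not detectable.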

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

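The tests of the axis within treatments and of the mitochondrial difference between colonies were chosen after these results were seen. If values were normally distributed, chance would flag about 1 in 20 groups of libraries when single libraries that stand apart are looked for. Of 39 groups examined, 7 held such a library, where 2 would be expected by chance at that rate, and the groups are not independent, since several share a library. Many of the groups are CPM of single models, most of them picked for large changes in these libraries, so the expected number is only a rough guide.

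Control 1A stood apart from the other control libraries in its composition factor, 0.714 against 1.04 to 1.23, a gap of 0.633 of the group's range. Its 50 most abundant models held 22.7% of its counts against 15.9% to 18.4% in the others, a gap of 0.631 of the range. LOC111347646 stood at 45.5 CPM in control 1A against at most 1.43 CPM in the other controls (0.975 of the range), and at 0.621 CPM in cUA 2C against at most 0.225 CPM (0.668). LOC111344807 and LOC111342923 stood at 12.1 and 11.9 CPM in cUA 2A, against at most 0.803 and 1.1 CPM in the other cUA libraries (0.934 and 0.915 of the range). LOC111339328 stood at 2.20 CPM in cGAMP 1B against at most 0.942 CPM (0.653 of the range).

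The cUA effect on the mitochondrial score differed between the colonies by -1.49, with -0.716 in colony 1 and 0.775 in colony 2 (exact permutation of colony labels within treatments, p = 0.005, adjusted p = 0.03 over 6 tests). With treatment labels permuted within colonies the exact permutation p was 0.01 and the adjusted p 0.06, so the difference depends on the choice of test. Neither permutation tests the interaction free of colony and treatment effects. The tables argue against a single library as the source. With each control or cUA library left out in turn the difference stayed at or beyond -1.26 in size (the value without cUA 2A), with exact permutation p-values of at most 0.025. The cGAMP libraries do not enter this difference, so leaving them out tests nothing. The tables also argue against the composition scaling as the whole cause, since with total counts only the difference was -0.937 (exact permutation p = 0.03). The composition of the libraries themselves stays open. cUA 2A and 2C, which carry the colony 2 rise, had the lowest composition factors of the cUA libraries (0.619 and 0.862). A difference between the colonies in their response to cUA, which the design could show, remains open and is a hypothesis. A wrong label on a single library is argued against as its source, since the difference was -1.84 without cUA 2B, -1.49 without cUA 1A, -1.52 without cUA 1B and -1.49 without control 1A. Wrong labels on several of them together were not tested and remain open.

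Within treatments the leading axis of variation, with 34.2% of the variance left after the treatment means, did not follow the colony labels. The tables argue against library depth, since all 18 of 18 libraries kept their side of the axis when thinned to equal depth, as did 16 of 16 in the analysis with neither control 1A nor cUA 2A. The scaling for composition stays open, since with total counts only 14 of 18 libraries kept their side, and cUA 1A and 1B, control 2C and cGAMP 2C crossed it. Of these all but control 2C moved to the side of their colony label, so that 3 libraries in place of 5 lay off it (control 1A, control 2C and cUA 2B). A mislabelled colony among the cUA libraries also stays open, and colony signatures could not decide it. A signature of 200 models per colony from the cGAMP libraries placed 5 of 6 control libraries on the side of their label. It did so for 3 of 6 cUA libraries, with cUA 1A, 1B and 2B on the other side. Every control and cUA library took the same side by that signature as on the axis. The signature was also built with cGAMP 2C, itself off its label on the axis. It thus reads the same variation again and is no separate evidence of wrong labels. A signature from the control libraries matched 5 of 6 cGAMP and 2 of 6 cUA libraries, but it also placed cUA 2A off its label, where the cGAMP signature did not. A signature from the cUA libraries matched 1 of 6 cGAMP and 2 of 6 control libraries. Differences between specimens that have nothing to do with labels remain open as well, and no biological explanation was tested.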

How the results depend on the processing

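The alternatives with surrogate variables, thinning, unweighted limma-voom, neither control 1A nor cUA 2A, and those for scores and neighbours were chosen after the data were seen. For cUA against control the 2179 calls became 3269 with DESeq2, 6144 with weighted limma-voom, 4906 with surrogate variables, 931 in colony 1 and 471 in colony 2, and 1369 to 3392 with a library left out (control 2A and control 1A). For cGAMP against control the 4604 became 10788 with weighted limma-voom, 7979 with surrogate variables, 7484 with neither control 1A nor cUA 2A, 2726 in colony 1 and 813 in colony 2, and 3567 to 6219 with a library left out. For cUA against cGAMP the 0 became 103 with DESeq2, 2836 with weighted limma-voom, 195 with surrogate variables, 729 with neither of the 2 libraries, 2 in colony 1, and 0 to 45 with a library left out (45 without cUA 2A). For the colonies it became 3 with DESeq2, 4510 with weighted limma-voom, 99 with neither of the 2 libraries, and 0 to 272 with a library left out (272 without control 1A). For the interactions DESeq2 gave 227 for cUA and 4 for cGAMP, weighted limma-voom 321 and 828, and leaving out a library 0 to 92 for cUA (92 without cUA 2B) and 0 for cGAMP. The single-colony fits hold fewer libraries; for the other shifts the cause was not tested. The remaining alternatives kept each count within 1.5 times.

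The correlation of fold changes fell from 0.86 to 0.643 with split controls, which removes the shared libraries and sets each compound against fewer controls, while the covariance went from 0.779 to 0.66; the correlation was 0.79 to 0.868 with a library left out. The score difference between cUA and cGAMP was -0.343 for models that rose and 0.504 for models that fell with neither control 1A nor cUA 2A, and -0.343 to -0.19 and 0.338 to 0.504 with a library left out. Control libraries do not enter this difference, so leaving out control 1A adds nothing to leaving out cUA 2A. In each of these the sets stayed those chosen from all 18 libraries. With treatment labels permuted within colonies the difference of models that fell, 0.391, passed (exact permutation test, adjusted p = 0.04). The cGAMP effect on the mitochondrial score was 0.834 to 1.18 and its colony difference for cUA -1.84 to -0.937 over all alternatives run.

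The letters do not pair the libraries: 6 of 18 same-letter pairs correlated above 0.1 (range -0.447 to 0.381) and 7 of 18 libraries correlated best with their own letter. With the letter as a replicate block the calls were 1674 for cUA, 4030 for cGAMP and 0 for cUA against cGAMP and both interactions.

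For the 12 named-model results, 378 of 400 alternative values kept direction and side of the threshold, 20 lost the call, 2 gained it (Cglr2 with surrogate variables) and 0 reversed. LOC111344807 and LOC111347646 got no value from DESeq2 or under the stricter filter. All 136 alternative values for neighbours stayed above chance. The planned gene list tests were not run, as no list had a member.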

Other observations

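The regions, the group of 123 models, the shares by model origin, the tests of neighbouring models and those by splits of the libraries were chosen after the results were seen; the counts of calls by edgeR, DESeq2 and weighted limma-voom were planned.

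Models that fell with both compounds also lay in runs. The longest held 11 adjacent tested models within 115 kb of NW_019217912.1 (424090 to 539482), which summed to 83.0 ± 22.6 CPM in seawater, 26.5 ± 11.8 CPM with cUA and 28.6 ± 10.8 CPM with cGAMP (SD, n = 6). Of the 5 fallen runs of 5 or more models, 2 lay on NW_019217806.1, at 736197 to 833351 and 852792 to 1047391, and the latter summed to 1350 ± 827, 326 ± 83.2 and 189 ± 43.3 CPM. The others were on NW_019217899.1 (214994 to 301842), from 14.4 ± 2.55 CPM to 2.24 ± 0.767 and 2.04 ± 1.08 CPM, and on NW_019218074.1 (55611 to 150094), from 9.86 ± 2.53 CPM to 1.72 ± 0.713 and 2.12 ± 0.676 CPM, the latter with all 6 models on the plus strand.

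A group of 123 models had a log2 fold change above 2 with cUA and was not called with cGAMP. It was spread over 98 scaffolds with at most 4 models on each. Within treatments its models varied together, with a mean pairwise correlation of 0.753 against at most 0.0765 in 1000 random sets, so they are not 123 separate responses. Another 130 models correlated above 0.8 with the group mean, of which 13 were called as higher with cUA and 2 with cGAMP. The group's mean log2 CPM ran from -1.54 to -0.291 in the control libraries, from -0.805 in cUA 1C to 3.32 in cUA 2A, and from -2.35 in cGAMP 2C to 1.24 in cGAMP 1B. Single libraries set these ends, as the next highest cUA library stood at 1.6 and the next lowest cGAMP library at -0.397, and choosing models by their cUA change favours those that are high in cUA 2A. The direct test of the compounds by edgeR called 0 of all tested models (1830 at an unadjusted p below 0.05; 103 by DESeq2, 2836 by limma-voom with sample weights), so the group is not shown to differ between them.

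Calls are also given by the origin of the gene model. Among tested models from AUGUSTUS 1.58% fell with cUA and 5.80% with cGAMP, against 4.46% and 12.8% of those from Gnomon, while 6.70% and 9.49% rose against 5.86% and 9.18%. These shares were not tested, and expression level was not accounted for.

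Adjacent models were called together beyond the permuted orders. Pieces of a single transcription unit counted as separate models do not account for all of it, since pairs on opposite strands and over 1000 bases apart also exceeded every permuted order, with a lowest ratio of 1.70 over the 4 lists of rises and falls. Such pieces may still add to the pairs on the same strand, whose ratio was higher than that of opposite strands by at least 2.41 standard errors in each list. An expression level shared by neighbours is argued against, since among orders permuted within bins of mean expression the lowest ratio was 1.96. Reads shared between similar copies side by side cannot be told apart from a response of the region with these files: the lowest ratio among neighbours whose coding lengths differ over 1.5 times was 1.89, but copies can be cut to unlike lengths and no sequence was compared. A response of whole regions, or of gene families that lie side by side, to cyclic dinucleotides remains a hypothesis.

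Whether chance could give such counts was examined with 55 splits of the libraries per comparison, the real one included. For cUA against control 1 split, the real one, gave as many as its 2179 calls, and the highest other gave 702. For cGAMP against control it was also 1, with 4604 calls against 2097 in the highest other. In both the real split gave the most calls of the 55 drawn, which makes chance unlikely but does not exclude it. For the remaining comparisons the real count was 0, which all 55 splits match by construction, so the splits say nothing about chance there: the highest other was 623 for cUA against cGAMP, 0 for the colony difference, 738 for the interaction with cUA and 0 for that with cGAMP. The splits with 623 and 738 calls show that groupings other than the real one can give calls. The median of the other splits was 0, 3 and 2 of them gave any call, and what sets those apart was not tested.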
